A study of Mus musculus with 31 samples.

How the data were processed

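Gene expression was measured in single mouse zygotes of the B6D2F1 background, 13 h after intracytoplasmic sperm injection (ICSI), in which a sperm is injected into the oocyte. Per the labels' protocols, messenger RNA of each single cell was captured on oligo-dT beads, copied into cDNA with random and oligo-dT primers, tailed and amplified by PCR before hybridisation to an oligonucleotide array. Metaphase II oocytes had received a control morpholino (n = 8), a morpholino against Oct4A (n = 7), mCherry cRNA (n = 8) or Oct4A cRNA (n = 8). A morpholino is an antisense oligomer that blocks translation or splicing of its target, and cRNA is RNA transcribed in vitro. The design text names 8, 12, 12 and 11 replicates, and the zygotes beyond the 31 used here were not analysed here. The labels call the zygotes biological replicates but name no female, injection session or array batch. The p-values therefore measure the spread between these zygotes alone.

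The authors deposited 1 normalized log10 intensity per probe and array, for 41174 probes. The logarithm's base is not stated in the sources used here. It was taken from the range of the deposited values, whose antilogarithm at base 10 spans the range of scanner intensities. The base scales every fold and SE printed here and leaves every p-value as it is. The submitters' processing notes name limma, with no version. Background correction and normalization methods are not given in the sources used here. The medians of the 31 arrays differed by at most 0.0158 on the log10 scale, so the arrays had been normalized to each other. Per the labels' protocols, a reference cDNA was labelled as well, with biotin. The labels also give biotin as the label of the samples themselves, so which channel the values come from is not settled by the labels. No detection calls were used here, so the background is unknown, and folds of dim probes may be compressed by it. The number of arrays limits the precision.

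Values were multiplied by 3.322 to give log2. The design fixed before the data were examined had assumed log2 or linear values, and only this conversion differs from it. Symbols came from the platform annotation, checked against the gene table of assembly GRCm38.p6, which was used for names alone. Of the probes, 32664 had 1 symbol, 45 had several and 8465 were unnamed here, and the identifiers of 140 probes were not found in the gene table, so their array symbol was kept. A feature was a gene, represented by its probe with the highest mean over all arrays, or a probe without a single symbol, which gave 28042 features. For 8511 genes this meant a choice among several probes.

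Differences were tested with limma (lmFit and eBayes, version 3.58.1, in R 4.3.3), in 1 fit of all 31 arrays with 1 mean per group, 27 residual and 2.81 prior degrees of freedom. The contrasts were Oct4A morpholino minus control morpholino, Oct4A cRNA minus mCherry cRNA, and the second minus the first. All tests were two-sided. A feature passed at a Benjamini-Hochberg adjusted p under 0.05 over all features. Pou5f1 was also tested by exact permutation of the zygotes. Gene lists fixed before the data were examined (21 lists, 799 of 860 members matched to the array) were tested with limma's camera at a preset inter-gene correlation of 0.01, with an estimated correlation and fry (change on balance in 1 direction, and change in either) beside it, adjusted over lists. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.

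The named genes follow a rule also set then. It takes Pou5f1; the 12 named features of smallest adjusted p per pair and direction among those that passed, filled up to 5 with features that did not pass; up to 4 passing members per list, or 2 not passing members of lists past the list test; and 5 per direction for the difference of effects. Zscan4c, Tcstv1, Pramel37 and the unnamed probes A_52_P152796 and A_52_P794346 were chosen after their values were seen. The same holds for Pou5f2, for other list members given by name, and for genes named in the comparison of both control groups.

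The analysis was tested on simulated data of the same size (28042 features, 50 changed per size). The simulated noise was normal, independent between features and of the same spread in all groups. In the morpholino pair, 16, 52, 68 and 94% of features changed by 1, 2, 3 and 4 on the log2 scale were recovered, and 5% of calls were false. In the cRNA pair, 12, 58, 88 and 98% were recovered, and 5.2% of calls were false. Under such noise the adjustment itself holds the share of false calls near its threshold. The real features are correlated and their spread differs between groups, so these rates need not hold for the real calls.

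Alternatives set before the data were examined were quantile normalization on top, centring on array medians, a filter on dim features, other summaries of probes, array weights, a trended and robust prior, the replicate number as a block, a fit of each pair alone, a 2-fold limit, and leaving out each array in turn. Leaving out both arrays of lowest weight was added after the data were seen. The overlap of calls against the shared control morpholino arrays was compared with simulations without effects and with splits of those arrays, also after the data were seen. The set of POU gene probes used to examine Pou3f2 was narrowed after its first result was seen, by dropping Pou2af1, a coactivator without a POU domain. The median log2 change was 0.08 over the first set of 15 probes and 0.01 over the remaining 14.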

Results

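Single zygotes carrying a block or an excess of Oct4A, a product of Pou5f1, were compared with zygotes injected with the matching control, 13 h after ICSI. Pou5f1 encodes Oct4, a POU-domain transcription factor of pluripotent cells and the germline, and Oct4A is one of its isoforms. The design contains 2 such comparisons that share no arrays. Levels are normalized log2 intensities, given as mean ± SD over zygotes, and differences are on the log2 scale with the standard error (SE) of the limma fit. The median correlation of a zygote with the others of its group was 0.887 ± 0.013 (SD, n = 8) in the control morpholino group, 0.886 ± 0.0046 (n = 7) with the Oct4A morpholino, 0.891 ± 0.0078 (n = 8) with mCherry cRNA and 0.892 ± 0.0073 (n = 8) with Oct4A cRNA. The median SD of a feature over zygotes was 0.91, 0.83, 0.81 and 0.83 in the same order. The highest correlation of any 2 arrays was 0.914, so no array repeated another.

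Pou5f1, represented by a single probe, stood at 14.66 ± 0.12 (SD, n = 8) with mCherry cRNA and 15.03 ± 0.06 (n = 8) with Oct4A cRNA. The difference was 0.37 (SE 0.13), and all 8 Oct4A cRNA zygotes lay above all 8 mCherry zygotes (exact permutation p = 0.000155, the smallest that the 12870 splits can give). In the limma fit the unadjusted p was 0.00636 and the adjusted p over all features was 0.424, which did not pass. The probe was among the 24 brightest of its array in every Oct4A cRNA zygote and ranked first in 1 of them, against ranks 36 to 123 with mCherry cRNA, so the upper end of the scale limits the difference that could be seen. In the morpholino pair Pou5f1 was 14.71 ± 0.05 (n = 8) with the control and 14.64 ± 0.13 (n = 7) with the Oct4A morpholino, a difference of -0.06 (SE 0.13) that was within the spread (exact permutation p = 0.233 over 6435 splits). A morpholino that blocks translation need not lower its target's mRNA, so this value does not measure the block.

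**Figure D1:**
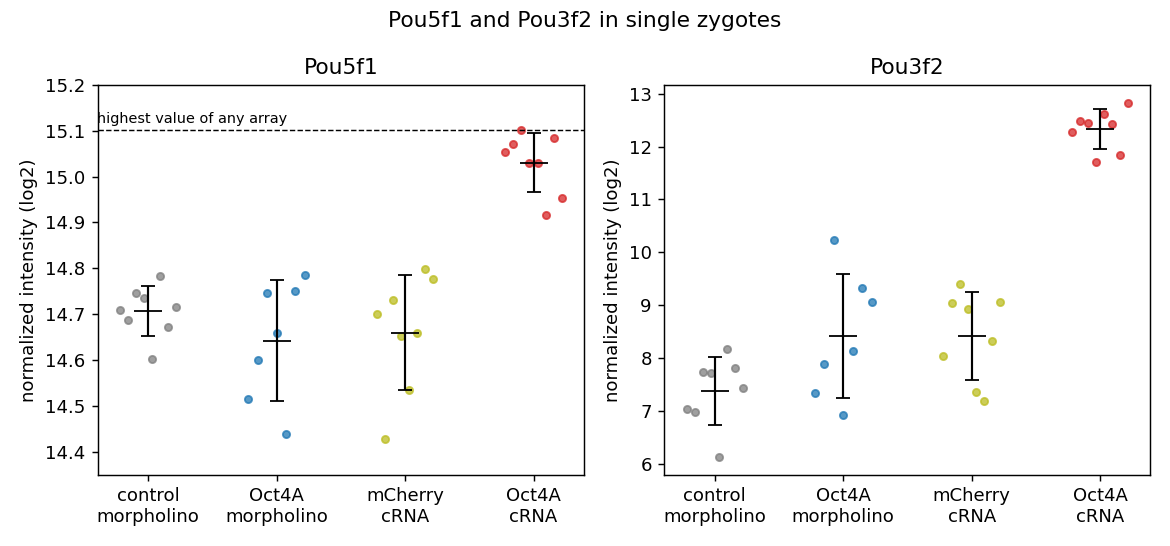
Normalized log2 intensity of Pou5f1 (left) and Pou3f2 (right) in each zygote of the 4 groups, with 1 point per zygote and bars for the mean and SD. Pou5f1 averaged 15.03 with Oct4A cRNA, close to the highest value of any array (dashed line), and Pou3f2 averaged 12.33 with Oct4A cRNA against 8.42 with mCherry cRNA.

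The cRNA pair asks which transcripts differ when extra Oct4A is supplied. Several genes of the 2-cell programme fell with Oct4A cRNA, while 11 of the 19 measured members of the list described below did not pass. Usp17le, Usp17lb and Usp17lc, which encode deubiquitinating enzymes of a multicopy family, fell, with differences of -3.42 (SE 0.34), -5.82 (SE 0.63) and -2.91 (SE 0.34), and Usp17lb went from 10.93 ± 1.34 to 5.11 ± 1.79 (SD, n = 8 in each group). Zscan4c, a zinc-finger gene known for its burst of expression at the 2-cell stage, fell by 3.16 (SE 0.44), and Tcstv1, another 2-cell gene, fell by 1.75 (SE 0.34). The related predicted genes Gm5662, Gm8300 and Gm4340 fell, with differences of -3.24 (SE 0.37), -2.04 (SE 0.24) and -2.12 (SE 0.26). Pou3f2, a POU factor best known from neural cells, rose from 8.42 ± 0.83 to 12.33 ± 0.38, a difference of 3.91 (SE 0.39).

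In limma, 55 of 28042 features passed, 5 higher and 50 lower with Oct4A cRNA, each by at least 2-fold, and 37 of them had a single gene symbol (4 higher, 33 lower). At an unadjusted p under 0.05 there were 1894. The adjusted p was 2.39e-07 for Usp17le, 1.23e-06 for Usp17lb, 7.26e-05 for Zscan4c, 0.011 for Tcstv1 and 2.48e-07 for Pou3f2. Gm7969 (-3.24, SE 0.29) and Gm2381 (-3.55, SE 0.35), both predicted genes, fell as well. So did Pramel39 (-3.89, SE 0.47) and Pramel37 (-3.97, SE 0.57) of the Prame-like family. Klk9, a kallikrein-related peptidase gene (-2.85, SE 0.37), the orphan receptor gene Gpr139 (-3.63, SE 0.48) and the apolipoprotein L gene Apol7a (-5.30, SE 0.70) also fell. Apol7a averaged 2.65 ± 0.89 with Oct4A cRNA, and was also low in control morpholino replicates 6 (2.25) and 8 (3.94). The unnamed probe A_52_P152796 fell by 6.26 (SE 0.35), from 10.18 ± 0.51 to 3.91 ± 0.70, with an adjusted p of 3.45e-13.

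Among features higher with Oct4A cRNA, Adarb1, which encodes an RNA-editing adenosine deaminase, rose by 3.01 (SE 0.62), the cytochrome P450 gene Cyp3a44 by 1.82 (SE 0.39) and Lrrc69 by 1.41 (SE 0.31). These 3 calls were lost on leaving out 1 array in 5, 10 and 21 of the 31 cases. Cyp3a44 went from 2.15 ± 0.28 to 3.97 ± 1.43 and Lrrc69 from 2.96 ± 0.49 to 4.37 ± 0.51. Both stayed below the median feature level of 4.74, so they are dim. The fifth feature that rose was the unnamed probe A_52_P794346, by 1.45 (SE 0.28). Ttc5 was higher by 2.47 (SE 0.58) but did not pass (limma adjusted p = 0.0743). Probes of the Usp17l, Zscan4, Tcstv and Pramel families and of the Gm5662 group can bind near-identical copies, so the values may belong to the family and not to the named copy. The second probes of Gm5662 and Gm8300 differed by -3.72 and -4.49, while 2 dimmer probes of Gm2381 (-0.18 and 0.69) and dimmer second probes of Apol7a (0.57) and Gpr139 (-0.28) did not pass. Of 2 further Tcstv1 probes, 1 differed by -2.07 and passed and 1 by -0.57 and did not. Other probes that did not pass were 1 of Zscan4c (-1.12), 2 of Adarb1 (0.69 and -0.11) and 1 of Cyp3a44 (-0.09).

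Of 19 measured members of the minor genome activation and 2-cell list, none rose, 8 fell and 11 did not pass, and 10 fell when adjusted over the list alone. The list's median difference was -1.75 (camera adjusted p = 1.73e-23; adjusted p = 5.78e-05 with an estimated correlation; fry adjusted p = 7.49e-08). Its mean per zygote was 9.71 ± 0.35 (SD, n = 8) with mCherry cRNA and 8.10 ± 0.36 (n = 8) with Oct4A cRNA, and no zygotes overlapped (exact permutation p = 0.000155, the smallest the splits can give). The 2 members that passed over the list but not over all features were Usp17la (-3.08, SE 0.78) and Eif1a (-1.86, SE 0.74). Duxbl1 differed by 0.02, Pramel13 by 0.26, Arg2 by -0.24, Sp110 by 0.52, Tdpoz1 by 0.43 and Zfp352 by -0.73, and none of these passed. Pramel6, Pramel7 and Tcstv3 did not pass either, and the 3 Pramel members of the list had a median of 0.02.

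**Figure D2:**
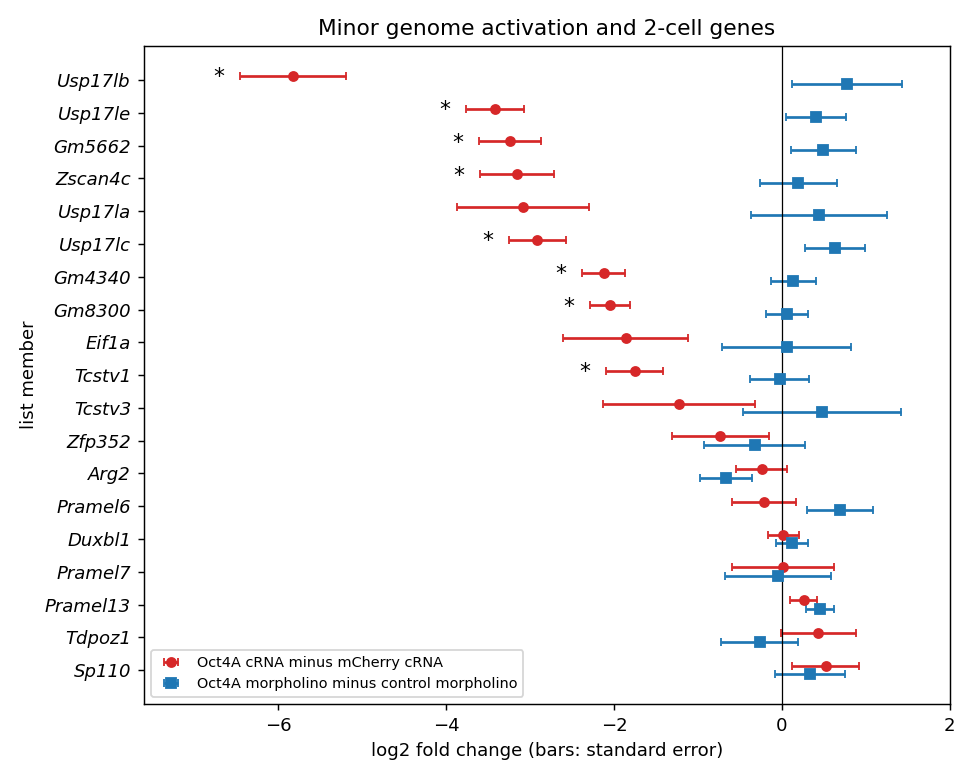
Log2 difference, with SE bars, of the 19 measured members of the minor genome activation and 2-cell list in the cRNA pair (red circles) and the morpholino pair (blue squares), where an asterisk marks an adjusted p under 0.05 over all features in the cRNA pair. The 8 marked members lie between -1.75 and -5.82 in the cRNA pair.

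Cytoplasmic ribosomal protein genes were lower on balance with Oct4A cRNA, with a median of -0.26 and 50 of 68 members below 0 (camera adjusted p = 0.00743). With an estimated correlation this list no longer passed (adjusted p = 0.427), and no member passed over all features. Rpl10 differed by -0.92 (SE 0.31) and Rpsa by -1.94 (SE 0.74). The remaining 19 lists did not pass camera in the cRNA pair, and of these fry called the heat shock and unfolded protein list (adjusted p = 0.0475). Fry's test for change in either direction, which does not compare a list with other genes, called the p53 and DNA damage list (adjusted p = 4.65e-05; mean -0.33) and of the 21 lists otherwise only the minor genome activation and 2-cell list (adjusted p = 2.34e-11). In the p53 and DNA damage list Gadd45a (-3.09, SE 0.90) and Gadd45b (-2.90, SE 0.79) passed over the list alone and no member passed over all features. Major genome activation genes had a median of 0.11, maternal effect and oocyte genes 0.03, maternal mRNA clearance factors 0.05 and the pluripotency network -0.06. Medians were -0.24 for trophectoderm genes and 0.08 for primitive endoderm genes. They were -0.08 for oxidative phosphorylation, 0.11 for the proteasome, -0.07 for the spliceosome, -0.03 for DNA replication and 0.09 for mitosis. The p53 and DNA damage list had -0.02, the interferon list 0.06, the heat shock and unfolded protein list -0.18, chromatin regulators 0.04 and apoptosis regulators -0.15. The mean had the opposite sign to the median in 4 of these lists, at -0.08 for major genome activation (camera direction up), -0.05 for primitive endoderm (down), 0.07 for DNA replication (up) and -0.02 for interferon (down). Among markers of other cells, cumulus and granulosa genes had a median of -0.07, sperm genes -0.02 and blood genes 0.12. The blood list's Fcer1g, an Fc receptor chain, fell by 2.63 (SE 0.55, limma adjusted p = 0.0286), a call lost in 10 of the 31 cases with 1 array left out, and 15 other members did not pass. Its dimmer second probe differed by 0.21.

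**Figure D3:**
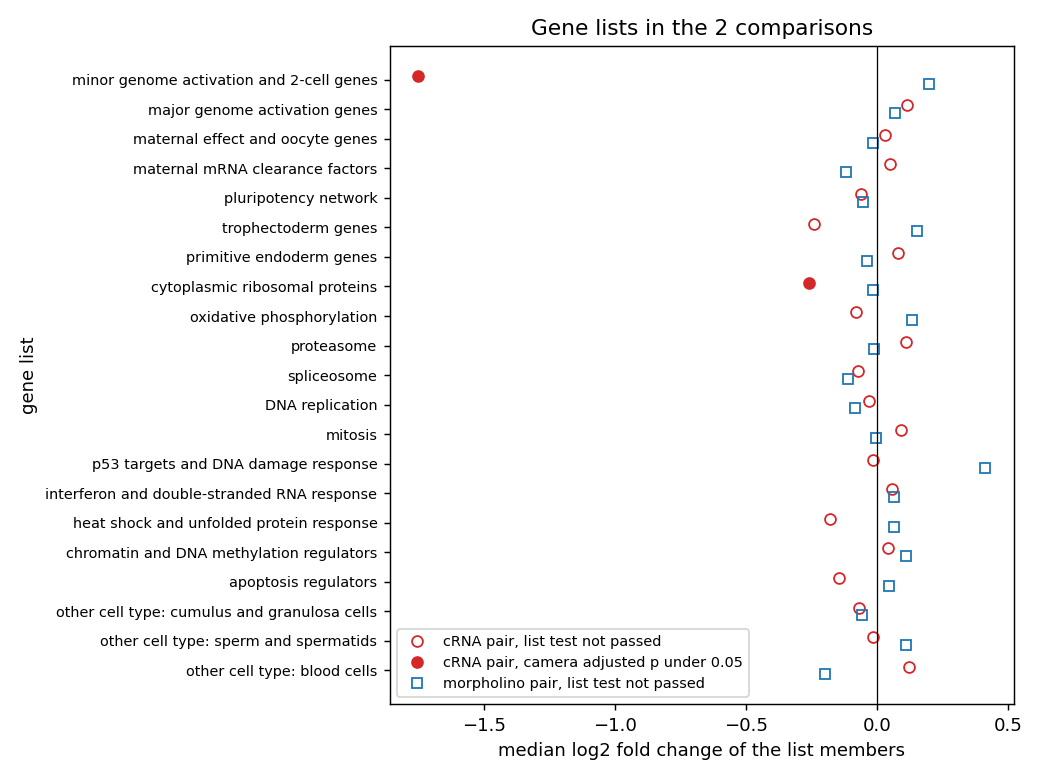
Median log2 difference of the members of each of 21 gene lists in the cRNA pair (red circles) and the morpholino pair (blue squares), filled where camera's adjusted p was under 0.05. The minor genome activation and 2-cell list stands at -1.75 in the cRNA pair and 0.20 in the morpholino pair.

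The morpholino pair asks which transcripts differ when Oct4A is blocked. Nudt16l2 rose by 2.94 (SE 0.47), from 5.51 ± 0.89 (SD, n = 8) to 8.45 ± 1.03 (n = 7), and Adamts16, a secreted metalloprotease gene, rose by 2.28 (SE 0.36). Txnrd2, the mitochondrial thioredoxin reductase, rose by 2.14 (SE 0.39), Crem, a cAMP-responsive transcription factor, by 2.58 (SE 0.52), and the receptor tyrosine kinase gene Tyro3 by 1.25 (SE 0.22). Rbfox2, a splicing regulator (-1.18, SE 0.22), and Thap11, a zinc-finger gene required in embryonic stem cells (4.00-fold), fell. So did Marchf9, a ubiquitin ligase gene (-3.25, SE 0.60), Wdr44 (-2.98, SE 0.56), Scube1 (-3.03, SE 0.58), the Krüppel-like factor gene Klf10 (2.82-fold) and 1600029O15Rik (-1.28, SE 0.23). Scube1 stood at 5.99 ± 2.11 with the control, 2.96 ± 0.45 with the Oct4A morpholino and 3.53 in both cRNA groups. Its control mean was thus the farther from the cRNA groups, as in 20 of the 32 features that passed. Of the features that fell, only Scube1 and 1600029O15Rik were among these 20, and the rest of the 20 rose.

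In limma, 32 features passed, 23 higher and 9 lower with the Oct4A morpholino, and 25 had a single gene symbol (18 higher, 7 lower). At an unadjusted p under 0.05 there were 2220. The adjusted p was 0.00847 for Nudt16l2 and Adamts16, and between 0.0204 and 0.0475 for the other named genes. The remaining named genes that rose were Ccl20 by 2.74, Lpin1 by 2.16, Scml4 by 2.05, Sbpl by 1.91, Spata46 by 1.89, Slc15a3 by 1.87 and Prrg2 by 1.60. No other probe of a named gene passed in this pair. A second Tyro3 probe had the opposite sign (-1.18) and another differed by 0.80. Second probes differed by -0.32 for Adamts16, 0.23 for Nudt16l2, -0.64 for Prrg2, 0.17 for Scml4, -0.69 for Rbfox2 and -0.60 for Wdr44. Further probes differed by 0.75 and 0.20 for Txnrd2, by -0.32 to 1.79 for 3 probes of Lpin1, by -0.11 and -0.32 for Scube1 and by -0.05 to 0.85 for Crem. The balance depended on the fit, with 20 features higher and 21 lower with array weights, and 8 higher and 14 lower with a trended robust prior. The count was 0 when the pair was fitted alone and ranged from 5 to 64 on leaving out 1 array, and Nudt16l2 and Adamts16 alone among the named genes kept their call without each array.

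None of the 21 lists passed camera in the morpholino pair. The p53 and DNA damage list had the smallest camera p, with a median of 0.41 and 21 of 30 members above 0 (adjusted p = 0.268). It alone passed fry's test for either direction (adjusted p = 0.00551), and Perp (2.29, SE 0.68) and Rprm (1.12, SE 0.35) passed over the list alone. Members of several other lists also passed over their list alone, with 2 in the primitive endoderm list. The minor genome activation and 2-cell list had a median of 0.20, with 14 of 19 members above 0 (adjusted p = 0.626). Its mean per zygote was 9.80 ± 0.45 (SD, n = 8) with the control and 10.01 ± 0.36 (n = 7) with the Oct4A morpholino, a difference within the spread (exact permutation p = 0.342).

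The effects of extra Oct4A and of its block were set side by side in the same fit. Gm7969, Gm2381, Usp17le, Usp17lc and Usp17lb had lower cRNA than morpholino effects, by -3.73 (SE 0.41), -4.02 (SE 0.50), -3.82 (SE 0.49), -3.54 (SE 0.49) and -6.59 (SE 0.91). Pou3f2, Adarb1, Marchf9, Rbfox2 and 1600029O15Rik had higher ones, by 2.87 (SE 0.57), 4.39 (SE 0.89), 4.14 (SE 0.84), 1.59 (SE 0.30) and 1.83 (SE 0.33). Each of these features passed in a single pair. Marchf9, Rbfox2 and 1600029O15Rik passed in the morpholino pair, with limma adjusted p of 0.863, 0.763 and 0.631 in the cRNA pair. The others passed in the cRNA pair, with limma adjusted p from 0.482 to 0.838 in the morpholino pair. Nor were all effects of opposite sign. Pou3f2 was also higher with the Oct4A morpholino, by 1.04 (SE 0.41, limma adjusted p = 0.482), and the probe A_52_P152796 was also lower with it (-1.47, SE 0.36, limma adjusted p = 0.0879), and neither passed in that pair. In limma, 80 features passed, 15 with a higher and 65 with a lower cRNA effect. The count was 51 without mCherry cRNA replicate 2 or Oct4A cRNA replicate 8, and 53 without mCherry cRNA replicate 6 or Oct4A cRNA replicate 7. Of the lists, the minor genome activation and 2-cell genes passed camera for the difference, with a median of -1.73 (adjusted p = 1.04e-16, and 0.000706 with an estimated correlation). The cRNA effect was the lower in 15 of 19 members, and 7 of them passed over all features. Trophectoderm genes (median -0.58) and the p53 and DNA damage list (-0.60) missed camera's threshold, with adjusted p of 0.0504 and 0.0622. Each had an adjusted p of 0.0498 with an estimated correlation and 0.0244 in fry, and no member of either passed. The heat shock and unfolded protein list (-0.28) had an adjusted p of 0.119 in camera, 0.0818 with an estimated correlation and 0.0278 in fry. In either direction, fry called the minor genome activation and 2-cell list (adjusted p = 1.34e-09), the p53 and DNA damage list (9.37e-08), the interferon list (0.00597) and maternal effect and oocyte genes (0.00711). No feature was called in both pairs, where 0.0628 would be shared by chance. Across all features the effects of both pairs had a Pearson r of -0.01 and a Spearman rho of -0.02, and features are not independent replicates.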

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

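The tests of a single gene family, of the control morpholino group's position, of outlying values in replicate 6 and of the other POU probes were chosen after the results were seen; the others in this part were planned. Of 100 groups of zygotes examined for a value far from the rest, 3 held one, and chance gives about 1 in 20 groups. Replicate 6 of the control morpholino group had a median correlation of 0.858 with its group, against 0.883 to 0.898 in the others. Usp17lb stood at 7.86 in mCherry cRNA replicate 11, against 10.58 to 11.86 in the other zygotes of the group, and Usp17lc at 9.79 in mCherry cRNA replicate 12, against 11.20 to 12.11. The effects of both pairs differed in 80 features, and in the minor genome activation and 2-cell list by a median of -1.73.

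The fall of the minor genome activation and 2-cell list with Oct4A cRNA was set against 3 technical explanations. Poorer amplification of the Oct4A cRNA zygotes could lower other features of the same level alike. Of 10000 level-matched random lists 0% had a median as low, so the list fell beyond features of its level. The arrays had been normalized to each other, which removes a loss shared by all features, and the random lists held unrelated genes. Poorer amplification of these particular transcripts therefore stays open. Cross-hybridisation within a single gene family would limit the fall to that family. Members of 4 families fell, while 0 of 3 Pramel and 0 of 1 Tdpoz members of the list did. Outside the list, Pramel39 (-3.89) and Pramel37 (-3.97) fell, so the Prame-like family as a whole was not spared. Families were set by gene name without sequences, so cross-hybridisation inside each of them stays open. A few zygotes would leave the others in the mCherry range, and all 8 lay below it. The list mean was 9.80, 10.01 and 9.71 in the other 3 groups and 8.10 with Oct4A cRNA. A lower activity of these genes under extra Oct4A is a hypothesis; a difference in developmental timing or in the amount of injected RNA was not tested.

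For the features that differed in the morpholino pair, values were set against a shift of the control morpholino zygotes and against replicate 6. The control morpholino mean was farther from the cRNA groups than the Oct4A morpholino mean in 20 of 32 features. The reverse held in 12. Of the 9 features that fell, only Scube1 and 1600029O15Rik were among the 20. The others of the 20 all belonged to the 23 that rose. A shift of the control group therefore cannot be told apart from an effect of the block, least of all for the features that rose. Among the 32 features the median distance was 1.48 for the control and 0.81 for the Oct4A morpholino, and 11 of them also passed between both control groups, a comparison that shares the control morpholino arrays. Without replicate 6, 29 features passed, 21 of them among the 32, and all 32 kept at least 86.3% of their effect. The 32 were called with that array in the fit, and a feature driven by it would rarely pass, because its spread would be wide. The kept effects therefore do not decide whether that array contributed. Injection session or array batch may differ between the groups and was not testable.

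For the rise of Pou3f2, binding of injected Oct4A cRNA to the Pou3f2 probe would also be possible for other POU probes. The median change of 14 other POU gene probes was 0.0147, but they went both ways, with Pou5f2 at 1.26, so this decides nothing. The probe sequences were not used here, so a probe effect cannot be told apart from a rise of the transcript. Whether Oct4A acts on Pou3f2 stays untested.

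Random regroupings tested whether chance groups give results as large. In the morpholino pair 1 of 100 splits, the real one, gave as many as 32 features (highest other 5). In the cRNA pair 1 of 100 gave as many as 55 (highest other 26), and for the difference of effects 1 of 100 gave as many as 80 (highest other 1). No other split gave counts as large, but 100 splits cannot show a share below 1 in 100. The splits treat zygotes as exchangeable, although female, session and batch are unknown. On leaving out 1 array the morpholino count fell as low as 5, and it was 0 with the pair fitted alone. Chance is therefore not excluded for that count. Nor can chance be excluded for the number of lists in the cRNA pair, since 17 of 100 splits gave at least 2 (highest other 3). In the morpholino pair 0 lists passed, so 100 of 100 splits give as many by construction and this tests nothing (highest other 4). For the correlation of both effects, -0.0118, 75 of 100 splits lay as far from 0 (highest other 0.113).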

How the results depend on the processing

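Leaving out both arrays of lowest weight was chosen after the data were seen; the other settings were planned. The cRNA count kept within 1.5 times of 55 under each setting run (44 to 65 on leaving out 1 array). The morpholino count was 86 with only features above the median level, 9 with the mean of a gene's probes, 17 with every probe and 0 with the pair fitted alone; the cause was not tested. With array weights it was 41 (20 higher, 21 lower) and with a trended robust prior 22 (8 higher, 14 lower), so its balance of 23 higher and 9 lower turned. On leaving out 1 array it ranged from 5 to 64. It was 10, 16, 17 and 21 without control morpholino replicates 1, 2, 4 and 5; 7, 64, 15, 5 and 5 without Oct4A morpholino replicates 2, 4, 7, 8 and 12; 16, 17 and 19 without mCherry cRNA replicates 1, 2 and 6; and 52, 16 and 17 without Oct4A cRNA replicates 4, 6 and 7. On leaving out 1 array the difference count ranged from 51 to 90, with 51 and 53 without mCherry cRNA replicates 2 and 6 and 53 and 51 without Oct4A cRNA replicates 7 and 8. The cRNA lists past the test numbered 1 with an estimated correlation, and from 1 (without Oct4A cRNA replicate 7) to 4 (without mCherry cRNA replicate 11). Same-numbered zygotes deviated together weakly or not at all (correlations -0.031 to 0.0654, mostly above 0, best partner of the same number in 2 of 11). The numbers therefore gave no clear pairing, but a weak effect shared by number is not excluded. With the replicate number as a block the counts were 0 (morpholino), 38 (cRNA, 31 of the 55 shared) and 9 (difference), 1 cRNA list passed, and Pou5f1 in the cRNA pair had a difference of 0.37 that no longer passed an unadjusted 0.05. Median correlations within groups were 0.821, 0.812, 0.812 and 0.815 for features above the median level, in control morpholino, Oct4A morpholino, mCherry cRNA and Oct4A cRNA. Of the named features past the threshold (19 in the morpholino pair, 22 in the cRNA pair, 10 for the difference), 0 lost their call with quantile normalization. With array weights 1, 1 and 0 did, with the block 19, 6 and 7, and with the pair alone 19 and 3 in both pairs. Signal over background is unknown here, which limits statements on dim probes.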

Other observations

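The comparison of both control groups, the overlap of its calls and the test of opposite signs were chosen after the values were seen. Although both received a control, mCherry cRNA and control morpholino zygotes differed. Kcnip2, a potassium channel interacting protein gene, was higher by 5.03 (SE 0.58) with mCherry cRNA than with the control morpholino, and stood at 6.34, 6.19, 11.37 and 10.69 in the control morpholino, Oct4A morpholino, mCherry cRNA and Oct4A cRNA groups. Prox1, a homeobox gene, was higher by 1.90 (SE 0.26), Cacna2d2 by 2.35 (SE 0.35), Pak3 by 2.84 (SE 0.43) and Slc24a2 by 1.38 (SE 0.21), and 1600029O15Rik was lower (-1.21, SE 0.23). In limma 72 features passed (64 higher, 8 lower with mCherry cRNA), and 1 of 100 splits of these arrays gave as many (highest other 1). Of these, 11 were also called in the morpholino pair (10 higher and 1 lower than the control morpholino in both), where independent lists would share 0.0525 and 0.00257. Both comparisons use the same control morpholino arrays. In 50 simulations with no effect the overlap was 0, where calls are rare in any case. With these arrays split between the comparisons in each of 70 ways, the overlap had a median of 0 and a highest value of 2, with medians of 4.5 and 25 calls, so part of the overlap may come from the shared arrays, and 20 of the 32 morpholino calls had the control mean farther from the cRNA groups. Between Oct4A morpholino and mCherry cRNA zygotes 1 feature passed, Kcnip2 (-5.18, SE 0.61), and 1759 had an unadjusted p under 0.05. Injected material and any unlabelled session differ together between both arms, and these cannot be told apart.

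Of the 32 features called in the morpholino pair, 27 had the opposite sign in the cRNA pair. The cRNA zygotes played no part in setting the morpholino means, but they entered the shared spread through which the 32 were called. The splits below keep that choice of features fixed. Of the 32, those that rose with the block had a median of -0.26 with Oct4A cRNA, and those that fell had 0.41. Of the 12870 splits of the cRNA zygotes, 630 gave signs as uneven (exact permutation p = 0.049, highest other 31), so the excess lies at the edge of what chance gives. It may point to opposite effects of block and excess on these features, but the test was run after the count was seen and 2 of the 32 had an unadjusted p under 0.05 in the cRNA pair. For the 50 features that fell with Oct4A cRNA the signs were even, with 27 above 0 in the morpholino pair and a median of 0.06.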
